A study of Saccharomyces pastorianus with 12 samples.

How the data were processed

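Total RNA from the lager yeast Saccharomyces pastorianus, strain CB11, was measured on 12 single-colour Affymetrix arrays, 3 for each of 4 sampling times during a brewery propagation. Per the labels' protocols, cells were separated from wort by centrifugation at 4 °C, flash-frozen and stored at -80 °C, RNA yield and purity were read on a Bioanalyser, and biotin-labelled cRNA was made from total RNA with the array maker's reagents. The deposited values are linear intensity signals, 1 per probe set and array, for 10928 probe sets. GCOS 5.0 and MAS5 are named per the submitters' processing notes, with no parameters; detection calls and scanner images were not used here.

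The deposited intensity columns do not share a scale. The mean signal after trimming 2% of probe sets at each end was 100.08, 100.08 and 100.07 on the 4h arrays, as a global scaling to a common target gives, but ranged from 22.6 on 8h C to 377 on 0h C among the other arrays. The design fixed before the data were examined took the table as already scaled. Because it was not, quantile normalisation of the log2 signals over the tested genes was used for the reported values, a change made after the data were examined; the deposited values without any normalisation and centring each array on its median were run as alternatives. Levels are therefore relative within each array, and a change in total mRNA per cell cannot be read from them.

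Probe sets were named through a platform annotation table that can be old. Of the 10928, 5685 carried 1 Saccharomyces cerevisiae gene, 4916 carried 1 Schizosaccharomyces pombe gene, 46 carried several genes, 68 had no gene named and 213 were controls. The strain is a hybrid whose second parental genome is not the one the probes were designed on, so a signal sums whatever bound to the S. cerevisiae probes. The culture should hold no S. pombe RNA, so those probe sets served as the background of each array. One probe set stood for a gene, preferring those without an ending that marks shared probes and then the brighter one, which gave 5635 genes. Of these, 5503 had a mean log2 signal over the 12 arrays above the 95th percentile of the S. pombe means (a signal of 7.74) and were tested; 132 were left out as dim. A gene below the array's 95th percentile of S. pombe signals on all 3 arrays of a time was treated as not above background there. Its change is given as "at least N-fold": the bright group's mean against the dim group's mean, taking on each dim array the higher of the S. pombe threshold and the gene's own value. The number of arrays limits the precision of every value.

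Tests were made in R 4.3.3 with limma 3.58.1 (lmFit, contrasts, eBayes with trend), with 1 coefficient per time over all 12 arrays and 8 residual degrees of freedom. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 5503 genes, with no fold minimum. The 5 comparisons were 4h, 8h and 30h against 0h, 8h against 4h, and 30h against 8h, and an F test covered any difference between the 4 times. Changes are log2 differences of group means ± the limma standard error, n = 3 arrays per time. The labels describe triplicate samples from a vessel, with no statement that they came from separate propagations, so p-values measure only the spread between these samples, which may be technical. The fit pooled each gene's spread over the 4 times, although for some genes it differed between times. TDH3, for example, had an SD of 0.23 at 4h and 1.86 at 0h. For such genes the standard error and p-value at 4h against 0h can understate the 0h spread. No 2 arrays held identical values.

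The 37 gene lists were written before the data were examined, from textbook knowledge of yeast. The 36 with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 180 tests (36 lists and 5 comparisons), and again with a correlation estimated from the residuals of each list. Of the 77 list calls at the preset correlation, 2 held with the estimated correlation: the proteasome at 8h against 4h and the cytosolic ribosomal proteins at 30h against 8h. Genes named in the text followed a rule set beforehand: for each comparison the 8 largest rises and 8 largest falls that passed the test with arrays that did not overlap, the 4 members of each described list with the largest absolute change, and 21 genes chosen without regard to their values, of which FLO1 had no tested probe set. The largest rises and falls are named in full at 4h against 0h and 30h against 8h, with the chosen genes and the members of lists described there by their counts. Some of those genes were added to the text late, after their values were seen. For 8h against 4h and both late times against 0h, only some genes of that rule are named for length, a choice also made after their values were seen.

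The steps were tested on simulated data that took each gene's mean over all arrays and its pooled residual SD, with independent normal noise. Spreads that differ between times, as the real ones do, and correlation between genes were not simulated. Both simulated comparisons used the same means and SDs, so nothing in them is particular to the times they are named for. The rates below therefore need not hold for the real data. In the simulated 4h against 0h comparison of 5503 genes, 59 of 70 genes changed by 2 on the log2 scale were recovered, 16 of 54 changed by 1 and 2 of 76 changed by 0.5, with 4 false calls. In the simulated 30h against 8h comparison, 53 of 68, 8 of 65 and 0 of 67 were recovered, with 4 false calls. Alternatives chosen before the data were examined were quantile normalisation and median centring in place of the deposited scale, pseudocounts of 16 and 100, other background filters, eBayes without trend, only the 2 times compared, the replicate letter as a block, a 2-fold minimum, only probe sets without shared-probe endings, fry in place of camera, and leaving out each array in turn. Array weights, estimated gene by gene and by REML, which did not converge, and fits of the 0h and 4h arrays alone or the 8h and 30h arrays alone were added after the data were examined, when the deposited scale also became an alternative. The median change of all tested genes after quantile normalisation was 0.02, -0.13, -0.10, -0.12 and 0.02 for 4h, 8h and 30h against 0h, 8h against 4h and 30h against 8h. Figures were drawn with matplotlib. No genome coordinates were used.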

Results

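The series followed transcripts of the lager yeast strain CB11 through an industrial propagation, the aerobic stage in which a brewery grows yeast before fermentation, to describe how the yeast responded to the changing environment. Cells came from a 140 hl vessel that had been inoculated from an 8 hl vessel. The wort was 80% malt and 20% maltose adjunct at 17° Plato, supplemented to 0.5 mg per l zinc, held at 20 °C and oxygenated to keep 7 to 8 mg per l dissolved oxygen. Samples were taken at 0, 4, 8 and 30 h, with 3 samples (A, B and C) at each time and 1 array per sample.

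The early and late arrays differed in brightness and in range. The median tested gene had a deposited signal of 134, 205 and 421 at 0h, 96.6, 96.3 and 102 at 4h, 54.1, 52.7 and 31.5 at 8h, and 54.3, 75.9 and 70.1 at 30h. The SD of log2 signals over genes was 1.91 to 2.03 at 0h and 4h and 1.21 to 1.33 at 8h and 30h. Between 87.9% (8h C) and 98.5% (4h C) of tested genes exceeded the 95th percentile of S. pombe signals of their array. Spearman's rho over genes, which are not independent replicates, ranged from 0.205 to 0.402 between an early and a late array. It was 0.848 to 0.91 between 8h and 30h, and 0.649 to 0.822 between 0h and 4h. Within a time rho was 0.9905 to 0.9944 at 4h, 0.892 to 0.921 at 8h and 0.906 to 0.942 at 30h. At 0h it was 0.974 between B and C, but 0.729 between A and B and 0.764 between A and C. Array 0h A also had the lowest rho with the 4h arrays, 0.649 to 0.672.

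Of the 0h samples, A and C stood apart in RNA quality. The 3′ to 5′ signal ratio, a measure of how complete the labelled transcripts were, had a median over 8 control genes of 31.0 on 0h A and 6.53 on 0h C, against 1.87 on 0h B and 1.30 to 2.02 at the later times. Array 0h B had a spiked hybridisation control at 102, where the other arrays had 2312 to 9283. Divided by the median tested gene, that control was 0.498 to 65.4 at 0h and 22.6 to 29.7 at 4h. It was 151 to 207 at 8h and 108 to 167 at 30h, so yeast signals were weaker beside the control on the late arrays. The cause was not tested.

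**Figure D1:**
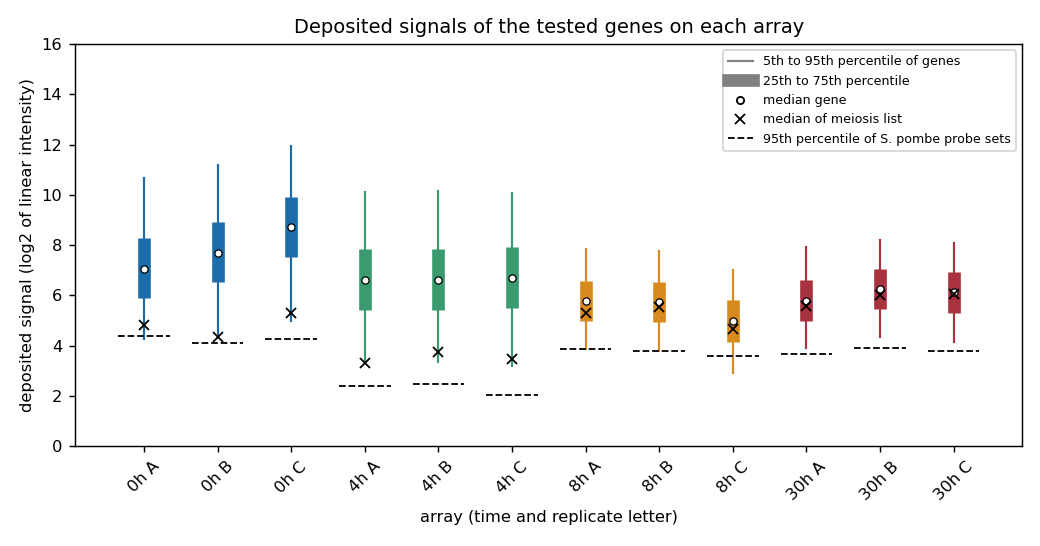
Deposited log2 signals of the 5503 tested genes on each of the 12 arrays, with the 5th to 95th and 25th to 75th percentiles as lines, the median gene as a circle, the median of the meiosis list as a cross and the 95th percentile of S. pombe probe sets as a dashed line. Relative to the median gene of the array, the meiosis list lay between -3.43 and -2.23 log2 units on the 0h and 4h arrays and between -0.44 and -0.08 on the 8h and 30h arrays.

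During the first 4 h in the vessel, genes for making ribosomes fell and genes for glycolysis, storage carbohydrates and maltose use rose. Of 64 tested ribosome biogenesis factors, the nucleolar proteins that process rRNA and assemble subunits, 51 fell and 0 rose, with a median log2 change of -1.91. Of 17 genes of glycolysis and ethanol formation, 14 rose and 0 fell, with a median of 1.69. The 4h against 0h comparison called 647 genes higher and 648 lower among 5503.

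Among called genes whose arrays did not overlap, the polyamine transporter gene TPO2 had the largest fall and fell by 4.18 ± 0.31 on the log2 scale (adjusted p = 4.87e-06, limma). FYV7 and CGR1, both of rRNA processing, fell by 3.57 ± 0.35 and 3.32 ± 0.31. ARX1, which helps export the large ribosomal subunit, fell by 3.10 ± 0.25, and the ribosome-associated TMA16 fell by 2.997 ± 0.34. YBL028C fell by 3.36 ± 0.25, and the sporulation gene SPO19 fell by 3.56 ± 0.57 to a level above background on 1 of 3 arrays at 4h. The meiotic gene GMC2 was not above background at 4h and was at least 1.13-fold lower there, a call that ended with pseudocounts of 16 and 100 (adjusted p = 0.0758 and 0.468, limma). Within the biogenesis list, UTP13, SSF1 and RPF2 fell by 2.93 ± 0.23, 2.87 ± 0.39 and 2.70 ± 0.28. The nucleolar protein gene NSR1 fell by 1.92 ± 0.44 (adjusted p = 0.00726, limma). Adjusted over the list alone, 56 of the 64 members fell. The list was called at camera adjusted p = 6.91e-27, but with an estimated correlation its adjusted p = 0.13.

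Subunits of RNA polymerases I and III, which make rRNA and tRNA, moved the same way: 12 of 18 fell and 0 rose, 13 fell when adjusted over the list alone, and the median change was -1.36. RPC19 fell by 2.83 ± 0.26, RPA12 by 2.43 ± 0.42, RPA43 by 2.16 ± 0.29 and RPA34 by 2.13 ± 0.35. Camera gave adjusted p = 6.78e-08, and adjusted p = 0.238 with an estimated correlation, and with 1 array left out 8 (without 0h C) to 18 (without 0h A) were lower. Cytosolic ribosomal protein genes moved little by comparison, with 1 higher and 11 lower of 128 and a median of -0.18 (camera adjusted p = 0.0265, and adjusted p = 0.529 with an estimated correlation; 0 higher and 5 lower when adjusted over the list alone). With 1 array left out, 5 (without 4h A) to 15 (without 0h A) were lower. RPL22B fell by 1.78 ± 0.30, RPS27A by 1.48 ± 0.29 and RPS21A by 1.14 ± 0.24, while RPL3 rose by 1.17 ± 0.36 (adjusted p = 0.0303, limma). Median centring ended the list's call and those of RPL3 and RPS21A (adjusted p of 0.138, 0.073 and 0.089), and the list's call also ended without 0h B or 0h C (adjusted p = 0.147 and 0.07) and with fry (adjusted p = 0.0994). The change of RPL3 was 0.67 without 0h A, and its call ended without 4h A, 4h B, 4h C or 8h B (highest adjusted p = 0.105).

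Among the 17 glycolytic genes, TDH3, for glyceraldehyde-3-phosphate dehydrogenase, rose by 3.44 ± 0.65, ENO2, for enolase, by 3.38 ± 0.39, PGK1 by 2.84 ± 0.38 and GPM1 by 2.66 ± 0.24 (adjusted p of 0.00212 or lower, limma). All 17 rose when adjusted over the list alone. Camera gave adjusted p = 5.11e-11, and adjusted p = 0.2 with an estimated correlation. The 0h A array, with its 3′ to 5′ ratio of 31.0, lay apart from 0h B and C in this list and in ribosome biogenesis. Without it, 64 of 64 biogenesis factors were lower (median -2.10) and 13 of 17 glycolytic genes were higher (median 1.48). Without 0h C, 39 of 64 biogenesis factors were lower, the fewest with 1 array left out. With the 0h and 4h arrays fitted alone, 41 of 64 biogenesis factors were lower (median -2.36). In that fit 11 of 17 glycolytic genes were higher (median 1.90).

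Storage carbohydrate and stress genes also rose. Of 17 genes of trehalose and glycogen metabolism, 11 rose and 0 fell (median 1.17, camera adjusted p = 2.43e-06, and adjusted p = 0.0909 with an estimated correlation; 11 when adjusted over the list alone). GSY1, for glycogen synthase, rose by 2.03 ± 0.42, PGM2, for phosphoglucomutase, by 2.02 ± 0.32, the glycogen branching enzyme gene GLC3 by 1.74 ± 0.34 and GAC1 by 1.65 ± 0.32. TPS1, for trehalose-6-phosphate synthase, rose by 1.17 ± 0.24. Of 22 heat shock and general stress genes, 12 rose and 1 fell (median 0.99, camera adjusted p = 8.41e-05, and adjusted p = 0.2 with an estimated correlation; 12 higher and 2 lower when adjusted over the list alone), and 6 (without 4h B) to 13 (without 30h C) rose with 1 array left out. The chaperone genes SSE2, HSP42 and HSP104 rose by 2.12 ± 0.24, 2.02 ± 0.23 and 1.80 ± 0.22, and GRE3 by 1.76 ± 0.47, which was 1.16 without 0h A and not called without 4h B (adjusted p = 0.0522). HSP12 rose by 0.81 ± 0.25 (adjusted p = 0.0339, limma), not called with median centring (adjusted p = 0.112) nor without 0h B, 0h C, 4h A, 4h B or 4h C (highest adjusted p = 0.123), and HSP26 did not pass, at 1.02 ± 0.71 (adjusted p = 0.319, limma).

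Of 10 genes for use of maltose and other alpha-glucosides, the main wort sugars, 7 rose and 0 fell, both over all genes and adjusted over the list alone (median 1.07, camera adjusted p = 0.000357, and adjusted p = 0.0909 with an estimated correlation). The isomaltase genes IMA5 and IMA1 rose by 2.02 ± 0.25 and 1.84 ± 0.24, the maltose transporter gene MAL31 by 1.61 ± 0.21, MAL11 by 1.34 ± 0.27 and the maltase gene MAL32 by 0.93 ± 0.20. Several of these genes belong to families of similar copies, and the MAL32 probe set has an ending that marks shared probes. Some of the signals may therefore not be separate measurements. Of 16 TCA cycle genes, 9 rose and 0 fell (median 0.76, camera adjusted p = 0.000192, and adjusted p = 0.238 with an estimated correlation; 11 when adjusted over the list alone). FUM1, SDH2, SDH1 and MDH1 rose by 1.501 ± 0.38, 1.46 ± 0.46, 1.32 ± 0.28 and 1.17 ± 0.29, and CIT1, for citrate synthase, by 0.65 ± 0.21, not called with the replicate letter as a block (adjusted p = 0.0578) nor without 0h A, 0h B, 4h A, 4h B or 4h C (highest adjusted p = 0.127). With 1 array left out, 4 (without 4h B) to 11 (without 30h C) of the 16 were higher. Without 0h A the change of SDH2 was 0.71, and the call of SDH2 ended without 4h A, 4h B or 4h C (highest adjusted p = 0.102).

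Of 13 gluconeogenesis and glyoxylate genes, 4 fell and 0 rose, both over all genes and adjusted over the list alone (median -0.46, camera adjusted p = 0.00747, and adjusted p = 0.23 with an estimated correlation); without 0h A 6 fell. PCK1, for the gluconeogenic enzyme phosphoenolpyruvate carboxykinase, fell by 2.91 ± 0.23, SFC1 by 2.42 ± 0.39 and IDP2 by 1.32 ± 0.32, and FBP1 was at -1.34 ± 0.52 (adjusted p = 0.0764, limma), called with median centring and with a pseudocount of 100 (adjusted p = 0.0232 and 0.0411). Of 15 beta-oxidation and peroxisome genes, 3 rose and 0 fell, or 5 and 0 when adjusted over the list alone (median 0.75, camera adjusted p = 0.00512, and adjusted p = 0.13 with an estimated correlation). POX1, for the first enzyme of beta-oxidation, rose by 1.63 ± 0.23 and POT1, for its thiolase, by 1.06 ± 0.33, with DCI1 at 1.38 ± 0.48 (adjusted p = 0.0513, limma; called with median centring and a pseudocount of 16, at adjusted p = 0.0134 and 0.0494) and FAA2 at 1.29 ± 0.84 (adjusted p = 0.287, limma). The call of POT1 ended without 0h B, 0h C, 4h A, 4h B or 4h C (highest adjusted p = 0.108), and 1 (without 4h A) to 7 (without 0h A) of the 15 were higher with 1 array left out. Hexose transporters as a list were not called (camera adjusted p = 0.271; 0 higher and 2 lower of 16, also when adjusted over the list alone), but the glucose transporter genes HXT1 and HXT3 fell by 2.46 ± 0.25 and 1.29 ± 0.30, with HXT13 at 0.82 ± 0.45 and RGT2 at -0.81 ± 0.38 (adjusted p = 0.196 and 0.137, limma). Of 7 histone genes 3 rose and 0 fell (median 0.80, camera adjusted p = 0.000761, and adjusted p = 0.13 with an estimated correlation; 6 when adjusted over the list alone), and without 0h A 6 rose. HTB2 rose by 1.91 ± 0.22, HTA2 by 1.84 ± 0.23 and HHT2 by 1.30 ± 0.29, with HHT1 at 0.80 ± 0.28 (adjusted p = 0.0518, limma), called with median centring, pseudocounts of 16 and 100 and the replicate block (adjusted p of 0.0364, 0.0471, 0.0398 and 0.0401). The G1 cyclin gene CLN2 rose by 1.59 ± 0.44 and the mitotic cyclin gene CLB2 by 1.10 ± 0.27, and a pseudocount of 100 ended the call of CLN2 (adjusted p = 0.19). It also ended without 4h A, 4h B or 4h C (highest adjusted p = 0.0631), and that of CLB2 without 4h A (adjusted p = 0.0621).

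The other largest rises were FMP45, a cell cortex protein gene, at 3.73 ± 0.47 (adjusted p = 0.000128, limma), the protein kinase gene YPK2 at 3.30 ± 0.90 (2.15 without 0h A, and not called without 4h A or 4h B, at adjusted p = 0.0734 and 0.0698), the cell wall mannoprotein gene SRL1 at 3.25 ± 0.26 and SDS24 at 2.76 ± 0.36. PTH1, for a peptidyl-tRNA hydrolase, was not above background at 0h and was at least 2.92-fold higher at 4h. On the deposited scale the median gene changed by -1.17 and the fit called 45 genes higher and 2609 lower; median centring called 1025 and 907. Leaving out 4h A, B or C gave 336, 320 or 355 higher and 376, 353 or 385 lower calls, and leaving out 0h A gave 783 and 767.

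**Figure D2:**
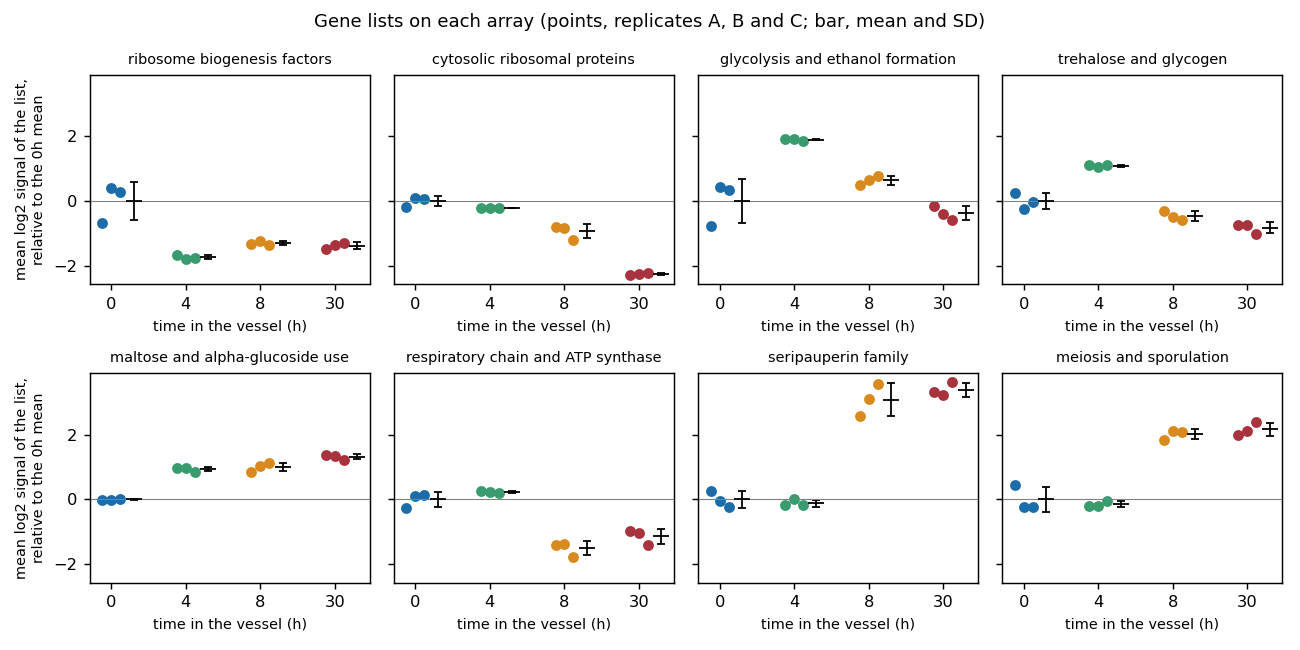
Mean normalised log2 signal of the members of 8 gene lists on each array, relative to the 0h mean of each gene, against time in the vessel in h; points are the 3 arrays of a time and the bar is their mean and SD. Ribosome biogenesis fell and glycolysis and trehalose and glycogen rose from 0h to 4h, cytosolic ribosomal proteins fell between 8h and 30h, and the seripauperin and meiosis lists separate the early from the late arrays.

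Between 4h and 8h the respiratory chain, proteasome, TCA cycle, stress and storage genes fell, and the seripauperin family, mating genes and meiosis genes rose. This comparison spans the change in brightness and range between the arrays. Of 31 respiratory chain and ATP synthase genes, 27 fell and 0 rose (median -1.91), and of 34 proteasome genes 28 fell and 2 rose (median -1.87). The fit called 1692 genes higher and 1863 lower, and no change below can be separated from that between the arrays.

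COX5A, COR1 and ATP2 of the respiratory chain and ATP synthase fell by 3.43 ± 0.48, 3.28 ± 0.40 and 2.97 ± 0.41, and ATP3 fell by 3.004 ± 0.35 (camera adjusted p = 3.11e-06, and adjusted p = 0.2 with an estimated correlation; 27 when adjusted over the list alone). The proteasome was the list called at 8h against 4h with either correlation (adjusted p = 7.44e-07, and adjusted p = 0.0493 with an estimated correlation; 29 lower when adjusted over the list alone). Its subunit genes PRE9 and PUP3 fell by 3.78 ± 0.35 and 3.76 ± 0.58. Of 16 TCA cycle genes, 15 fell and 1 rose, LSC1 by 2.73 ± 0.34 and LSC2 by 2.71 ± 0.23 among them (camera adjusted p = 0.000204, and adjusted p = 0.238 with an estimated correlation; 15 lower when adjusted over the list alone). Trehalose and glycogen genes fell in 13 of 17 cases and rose in 2, with GSY1 and PGM2 falling by 4.12 ± 0.42 and 3.23 ± 0.32 and TPS1 by 2.41 ± 0.24 (camera adjusted p = 0.00149, and adjusted p = 0.2 with an estimated correlation; 13 lower when adjusted over the list alone). Of 22 stress genes 15 fell and 2 rose, or 16 and 2 when adjusted over the list alone (camera adjusted p = 0.0013, and adjusted p = 0.238 with an estimated correlation). The chaperone gene SSA4 was not above background at 8h and was at least 4.44-fold lower, and SSA3 and HSP26 fell by 3.71 ± 0.55 and 3.50 ± 0.71.

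Glycolytic genes fell in 14 of 17 cases, also when adjusted over the list alone, and in 8 without 8h A, GLK1 by 3.02 ± 0.50 and PGI1 by 2.40 ± 0.27 (camera adjusted p = 0.00393, and adjusted p = 0.464 with an estimated correlation). Ergosterol synthesis, several steps of which need oxygen, fell in 18 of 24 genes and rose in 2, over all genes and adjusted over the list alone, with HMG1 falling by 3.29 ± 0.36 and ERG10 by 3.11 ± 0.46 (camera adjusted p = 0.000556, and adjusted p = 0.375 with an estimated correlation). ERG3 fell by 2.06 ± 0.28. Of 128 cytosolic ribosomal protein genes, 57 fell and 10 rose, over all genes and adjusted over the list alone, RPS0A by 3.95 ± 0.36 and RPL13A by 3.78 ± 0.74 among the falls (camera adjusted p = 0.00107, and adjusted p = 0.375 with an estimated correlation). The largest falls were the histone chaperone gene NAP1, at least 18.5-fold lower, and SBA1, for an Hsp90 co-chaperone, which fell by 5.51 ± 0.60. Others were MRPS12, which fell by 5.37 ± 0.78, ICL1 at least 3.55-fold lower, MXR2 at least 8.72-fold, MRPL20 at least 4.07-fold, YPK2 at least 9.11-fold and RSM7 at least 7.38-fold.

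Of 13 tested seripauperin genes, subtelomeric copies too alike for their signals to be told apart with certainty, 12 rose (median 3.60, camera adjusted p = 6.33e-06, and adjusted p = 0.238 with an estimated correlation; 12 when adjusted over the list alone). PAU21, PAU18 and PAU24 rose by 5.87 ± 0.36, 4.84 ± 0.40 and 4.47 ± 0.29. Mating genes, markers of haploid cells, rose in 18 of 21 cases, also when adjusted over the list alone (median 2.68, camera adjusted p = 2.43e-06, and adjusted p = 0.238 with an estimated correlation), with FIG1, the pheromone gene MFA2 and the receptor gene STE3 rising by 5.69 ± 0.82, 4.98 ± 0.46 and 4.67 ± 0.42. Meiosis genes rose in 20 of 25 cases, or 21 when adjusted over the list alone (median 1.67, camera adjusted p = 3.51e-06, and adjusted p = 0.238 with an estimated correlation), with SPS4 and SPO21 rising by 4.77 ± 0.37 and 4.52 ± 0.32. Hexose transporters rose in 11 of 16 cases and fell in 2, also when adjusted over the list alone (camera adjusted p = 0.00638, and adjusted p = 0.238 with an estimated correlation), with HXT14, GAL2 and HXT8 rising by 5.07 ± 0.47, 4.57 ± 0.35 and 4.19 ± 0.35 and HXT1 by 1.44 ± 0.25.

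Beside these rises stand measured differences between the arrays. On the 8h and 30h arrays the medians of the meiosis and mating lists lay between -0.44 and 0.295 log2 units from the median gene, against -3.75 to -1.76 on the 0h and 4h arrays. Genes with only a systematic name made up 17.4% of the genes higher at 8h than at 4h, 6.98% of those lower, and 11.4% of all tested. Of 57 genes not above background on any 4h array, 47 were above it on all 3 arrays at 8h and 54 at 30h.

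Among the largest rises at 8h, YDL159W-A was at least 158-fold higher, the meiotic genes SAE3 and GMC2 at least 66.5-fold and 14.5-fold, and ECM7 at least 14.1-fold. The meiotic splicing factor gene MER1 rose by 7.79 ± 0.48, YBR219C by 8.22 ± 0.95, YNL146C-A by 6.85 ± 0.43 and DGR1 by 6.83 ± 0.48. On the deposited scale the median gene changed by -1.28, with 603 genes called higher and 2842 lower.

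Against 0h, ribosomal protein and respiratory chain genes were lower at both late times and maltose genes were higher. Both comparisons span the change in brightness, range and order of genes between the early and late arrays, with rho at most 0.402 between them, and the lists below cannot be separated from it. At 8h, 1629 genes were higher and 1812 lower, and at 30h 1715 were higher and 1830 lower. Cytosolic ribosomal proteins fell in 77 of 128 cases at 8h, with 6 higher (median -0.91), and in 113 of 128 at 30h, with 0 higher (median -2.23). Maltose genes rose in 7 of 10 cases at 8h and 8 of 10 at 30h, with 1 lower at each time.

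RPS0A fell by 4.00 ± 0.36 at 8h and by 5.44 ± 0.36 at 30h, and RPL13A and RPL15A fell by 5.96 ± 0.74 and 4.56 ± 0.23 at 30h. Camera gave adjusted p = 3.11e-06 for the ribosomal proteins at 8h and 6.85e-21 at 30h, with adjusted p = 0.247 and adjusted p = 0.0909 with an estimated correlation; adjusted over the list alone, 78 and 113 fell. The maltose transporter gene MAL11 rose by 2.54 ± 0.27 at 8h and 3.21 ± 0.27 at 30h, MAL13 by 2.72 ± 0.26 and the invertase gene SUC2 by 2.19 ± 0.22 at 30h. For the maltose list, camera gave adjusted p = 0.0257 at 8h and 0.0154 at 30h, and adjusted p = 0.2 and 0.18 with an estimated correlation, with 7 and 8 members higher when adjusted over the list alone. Median centring ended both calls (adjusted p = 0.208 and 0.165), as did the deposited scale (adjusted p = 0.573 and 0.273), where the list's median change was -1.60 and -0.65 beside the shift of all genes. Respiratory chain genes fell in 27 of 31 cases at 8h, COX8 by 3.23 ± 0.31, and in 18 at 30h with 1 higher. Camera gave them adjusted p = 7.41e-06 and 0.00179, and adjusted p = 0.2 and 0.285 with an estimated correlation, with 27 and 17 lower adjusted over the list alone.

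ICL1, for isocitrate lyase of the glyoxylate cycle, was at least 4.21-fold lower at 8h and 7.43-fold at 30h, and IDP2 at least 26.5-fold lower at 8h. At 30h THS1, for threonyl-tRNA synthetase, and URA6 fell by 5.27 ± 0.34 and 5.54 ± 0.58. ERG3 fell by 2.90 ± 0.28 at 8h and 3.54 ± 0.28 at 30h. PAU21 rose by 5.14 ± 0.36 and 5.83 ± 0.36, and MER1 by 6.25 ± 0.48 and 6.31 ± 0.48; MAM1, of meiotic chromosome segregation, was at least 25.2-fold higher at 8h. The median gene changed by -2.48 at 8h and -1.86 at 30h on the deposited scale, with 221 higher and 4303 lower calls at 8h and 354 and 3635 at 30h.

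From 8h to 30h, cytosolic ribosomal protein genes fell: of 128 tested, 74 fell and 0 rose, with a median log2 change of -1.30. These 74 were part of 150 genes called lower, against 50 called higher, and 978 genes had an unadjusted p under 0.05. Of other lists, 4 of 7 histone genes, 7 of 17 glycolytic genes and 6 of 29 translation factor genes fell. Of 13 gluconeogenesis genes 3 rose, and of 22 stress genes 2 rose. Quantile normalisation with the early arrays, whose range was wider, can enlarge changes between the late arrays. With the 8h and 30h arrays fitted alone, 74 of 128 ribosomal protein genes fell, with a median of -1.02. Glycolysis then had 8 of 17 lower (median -0.729) and histones 2 of 7 (median -0.829). In simulated data, this comparison recovered 8 of 65 genes with a log2 change of 1, so a gene not called here may have changed.

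RPS28A, RPL3, RPL30, RPP1A, RPL2A, RPS11A and RPS31 were 7 of the 8 largest falls, with log2 changes from -3.49 to -2.84, each with an adjusted p of 0.000251 or lower (limma). RPL3 fell by 3.14 ± 0.36. The remaining gene, TIP1, for a cell wall mannoprotein, fell by 3.16 ± 0.29. Adjusted over the list alone, 95 ribosomal protein genes fell, and the list was called at camera adjusted p = 4.5e-61 and, with an estimated correlation, at adjusted p = 0.0252. Translation factors fell in 6 of 29 cases, or 9 adjusted over the list alone, with EFT2, TEF4 and STM1 falling by 1.86 ± 0.22, 1.84 ± 0.24 and 1.94 ± 0.33 and YEF3 at -1.48 ± 0.41 (adjusted p = 0.0649, limma). Camera gave the list adjusted p = 2.35e-05, and adjusted p = 0.306 with an estimated correlation, and with 1 array left out 3 (without 8h B) to 9 (without 0h A) fell. Ribosome biogenesis factors, which had fallen by 4h, had 0 of 64 called in either direction by limma and 9 at an unadjusted p under 0.05 (median -0.06, camera adjusted p = 0.58, fry adjusted p = 0.79; 0 also when adjusted over the list alone). Its largest changes were EMG1 at -1.66 ± 0.44, CBF5 at -0.95 ± 0.55, UTP9 at 0.86 ± 0.23 and NAN1, not above background at 8h (adjusted p of 0.0512, 0.398, 0.0501 and 0.341, limma). The replicate block called EMG1 (adjusted p = 0.0488), and pseudocounts of 16 and 100 called UTP9 (adjusted p = 0.0492 and 0.0377).

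Of 7 histone genes 4 fell, or 6 adjusted over the list alone (median -1.15, camera adjusted p = 2.83e-06, and adjusted p = 0.089 with an estimated correlation), HTA2 by 2.03 ± 0.23, HHF1 by 1.39 ± 0.26, HHT2 by 1.19 ± 0.29 and HHT1 by 1.15 ± 0.28. Median centring ended the calls of HHF1, HHT2 and HHT1 (adjusted p of 0.256, 0.288 and 0.338, limma). In the 12 fits without 1 array, 2 to 4 of the 7 fell, and the call of HHT2 ended in 9 and that of HHT1 in 7 (highest adjusted p = 0.135 and 0.12). Of 17 glycolytic genes 7 fell, or 9 adjusted over the list alone (median -0.998, camera adjusted p = 1.73e-08, and adjusted p = 0.238 with an estimated correlation). PDC1, for pyruvate decarboxylase, fell by 2.44 ± 0.28, PGI1 by 2.21 ± 0.27, FBA1 by 1.78 ± 0.28 and the alcohol dehydrogenase gene ADH1 by 1.75 ± 0.22. PGM2 and UGP1, the 2 of 17 trehalose and glycogen genes that fell, did so by 2.24 ± 0.32 and 0.94 ± 0.24 (camera adjusted p = 0.00928, and adjusted p = 0.238 with an estimated correlation; 2 also when adjusted over the list alone). TPS2 was at -0.63 ± 0.22 and NTH2 at -0.57 ± 0.25 (adjusted p = 0.147 and 0.261, limma). The call of UGP1 ended with median centring, the replicate block and pseudocounts of 16 and 100 (adjusted p of 0.17, 0.0721, 0.0609 and 0.106), and in 11 of the 12 fits without 1 array (highest adjusted p = 0.144). With 1 array left out, 1 to 3 of the 17 fell. The list's call ended without 30h C (adjusted p = 0.0617) and on the deposited scale (adjusted p = 0.0634).

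SIP18, induced by drying and osmotic stress, rose by 3.72 ± 0.50 (adjusted p = 0.000502, limma) and ECM4, for a glutathione transferase, by 3.37 ± 0.28. ART10 rose by 2.27 ± 0.39, the stationary-phase gene SPG4 by 2.17 ± 0.36, the autophagy gene ATG17 by 2.10 ± 0.33 and YMR175W-A by 2.40 ± 0.57. IDP2 and YER187W, not above background at 8h, were at least 2.71-fold and 1.14-fold higher. Of 13 gluconeogenesis and glyoxylate genes, 3 rose, or 4 adjusted over the list alone: IDP2, MDH2 by 1.03 ± 0.20 and PCK1 by 0.99 ± 0.23, with ACS1 at 0.75 ± 0.21 (adjusted p = 0.0721, limma). Camera gave the list adjusted p = 0.00215, and adjusted p = 0.197 with an estimated correlation, and its median of 0.44 was 0.29 without 30h A and 0.66 without 30h C. Stress genes rose in 2 of 22 cases, SPI1 by 1.68 ± 0.33 and MSC1 by 1.38 ± 0.28, or 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0482, and adjusted p = 0.395 with an estimated correlation). SSA3 was at 1.28 ± 0.55 and DDR2 at 1.03 ± 0.30 (adjusted p = 0.234 and 0.078, limma). The stress list's call ended without 8h B, 8h C, 30h A or 30h B (adjusted p of 0.123, 0.0734, 0.313 and 0.0679), with the replicate block (adjusted p = 0.0516) and with fry (adjusted p = 0.0878), and without 0h A 5 of the 22 rose. Of the respiratory chain, ATP15 and CYC1 rose by 1.43 ± 0.31 and 1.14 ± 0.28, the 2 of 31 that did, or 3 adjusted over the list alone, with COX13 at 1.24 ± 0.56 (adjusted p = 0.27, limma) and QCR9 at 1.07 ± 0.30 (adjusted p = 0.0688, limma). Camera gave that list adjusted p = 0.00444, and adjusted p = 0.306 with an estimated correlation, and its call ended without 8h C (adjusted p = 0.0606) and with fry (adjusted p = 0.058), with 0 of the 31 higher without 8h C and 5 without 0h A. With median centring, calls of 10 genes above ended: YER187W, YMR175W-A, IDP2, ART10, PCK1, MDH2, SPI1, MSC1, ATP15 and CYC1, at adjusted p from 0.0877 to 0.478. A pseudocount of 100 ended those of YER187W, IDP2 and PCK1 (adjusted p of 0.124, 0.243 and 0.0612), and the replicate block that of YMR175W-A (adjusted p = 0.053). In the 12 fits without 1 array, calls ended for CYC1 in 9, PCK1 in 8, YMR175W-A in 7, ATP15 in 2, and MSC1 and YER187W in 1 each, without 8h B and without 30h B (highest adjusted p of 0.15, 0.102, 0.099, 0.0766, 0.0591 and 0.07).

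The counts at 30h against 8h depended on the setting. Median centring called 6 higher and 43 lower (12.2% higher, against 25%), of which 6 and 42 were also called after quantile normalisation. The deposited scale called 3 and 2, and the fit without 0h A called 255 and 313. Without 4h A, B or C the higher calls were 28, 25 and 25, without 30h A or B 27 and 25, and without 8h A the lower calls were 99.

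Of 20 tested genes chosen beforehand for their interest to brewing, 13 were called between 0h and 4h. Among those not named above, ERG3, of ergosterol synthesis, fell by 0.84 ± 0.28 (adjusted p = 0.043, limma), a call that ended with the replicate block (adjusted p = 0.055) and in 8 of the 12 fits without 1 array (highest adjusted p = 0.154). Not called were ERG11, for lanosterol demethylase, at 0.16 ± 0.42 (adjusted p = 0.809, limma), the anaerobic gene DAN1 at 0.02 ± 0.41, HXT7 at -0.27 ± 0.38, the zinc transporter gene ZRT1 at -0.29 ± 0.35 and the histone gene HTB1 at 0.43 ± 0.28. CYC1 was at -0.70 ± 0.28 (adjusted p = 0.0844, limma), called with median centring (adjusted p = 0.017). The desaturase gene OLE1 rose by 1.18 ± 0.36, the mitochondrial superoxide dismutase gene SOD2 by 1.56 ± 0.42 and ATF1, of acetate ester formation, by 0.80 ± 0.22. Without 0h A, OLE1 was at 0.64 and not called (adjusted p = 0.0567), and SOD2 was at 0.996. Calls also ended without 4h A, 4h B or 4h C for OLE1 and ATF1 (highest adjusted p = 0.103 and 0.0832), without 4h A or 4h B for SOD2 (highest adjusted p = 0.0525), and with a pseudocount of 100 for ATF1 (adjusted p = 0.0687). ZRT1 fell by 1.37 ± 0.35 and ATF1 rose by 1.07 ± 0.22 from 4h to 8h. CLN2 rose by 2.57 ± 0.44 in that interval, and SOD2 fell by 1.41 ± 0.42, CIT1 fell by 1.90 ± 0.21, CYC1 fell by 0.98 ± 0.28 and RPL3 fell by 2.18 ± 0.36. The call of SOD2 there ended without 8h A (adjusted p = 0.0512).

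From 8h to 30h, RPL3 and CYC1 were the 2 of these 20 genes called. DAN1 was at 1.31 ± 0.41 (adjusted p = 0.105, limma), called with pseudocounts of 16 and 100 (adjusted p = 0.0438 and 0.0297). CLN2 was at 0.77 ± 0.44, HSP12 at 0.75 ± 0.25, HSP26 at 0.70 ± 0.71, ZRT1 at 0.33 ± 0.35, CLB2 at 0.23 ± 0.27, SOD2 at 0.23 ± 0.42, ATF1 at 0.20 ± 0.22 and ERG11 at 0.07 ± 0.42. MAL32 was at -0.11 ± 0.20, NSR1 at -0.27 ± 0.44, CIT1 at -0.33 ± 0.21, HXT1 at -0.34 ± 0.25, HXT7 at -0.47 ± 0.38, TPS1 at -0.50 ± 0.24, OLE1 at -0.56 ± 0.36, ERG3 at -0.65 ± 0.28 and HTB1 at -0.69 ± 0.28. Their adjusted p ran from 0.14 for HSP12 to 0.949 for ERG11 (limma). Across the change between the arrays, against 0h, RPL3 fell by 1.01 ± 0.36 at 8h and 4.15 ± 0.36 at 30h, where the 8h call ended without 0h B, 0h C, 8h B or 8h C (highest adjusted p = 0.117). The proteasome gene PRE9 fell by 3.88 ± 0.36 at 8h. CLN2 rose by 4.15 ± 0.44 at 8h and 4.92 ± 0.44 at 30h, DAN1 rose by 1.33 ± 0.41 at 30h, and HSP12 rose by 1.24 ± 0.25 at 30h but was at -0.485 with median centring (adjusted p = 0.318).

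**Figure D3:**
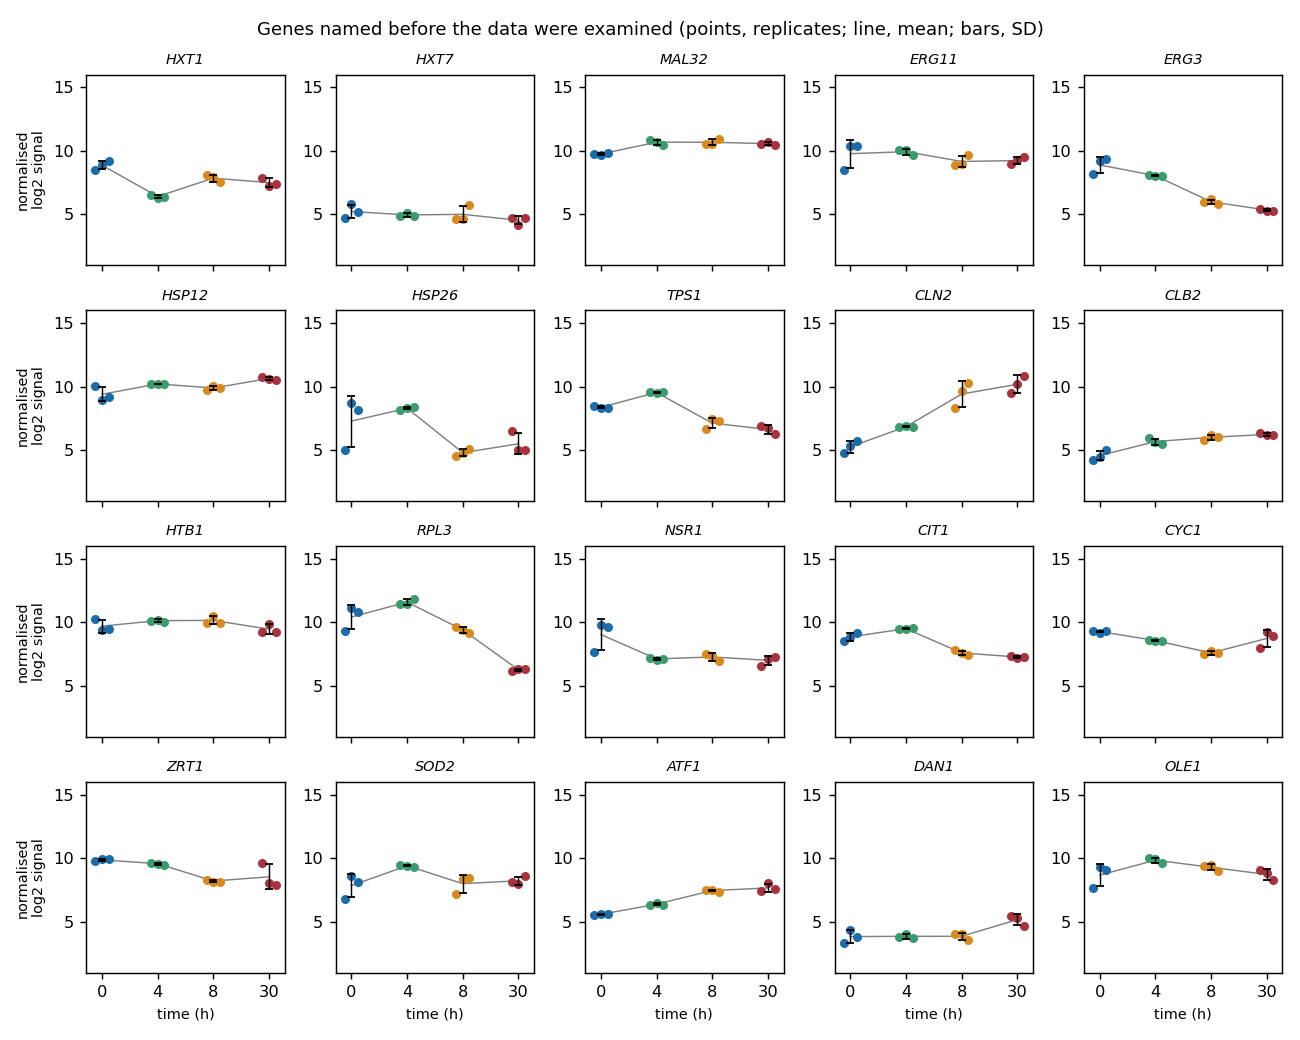
Normalised log2 signals of 20 genes chosen before the data were examined, against sampling time in h; points are the 3 arrays of a time, the line joins the means and bars are SD. NSR1 and HXT1 fell and TPS1 rose from 0h to 4h, TPS1 and CIT1 fell from 4h to 8h, and RPL3 fell by 3.14 log2 units from 8h to 30h.

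Over the 4 times, the limma F test called 4317 of 5503 genes (78.4%).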

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

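All tests of explanations below were chosen after the results they address were seen, and so were the limits that decided them.

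Probe sets for 18S rRNA, which the comparisons do not use, gave a median signal of 4090 on 0h B, 2688 on 4h A, 2791 on 4h B, 155 on 4h C and 35.27 on 0h C, above the 99th percentile of S. pombe probe sets on each of those arrays. Of 4916 S. pombe probe sets, which should have no target in the culture, 27 differed between the 4 times at a limma adjusted p under 0.05.

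The 8h and 30h arrays ranked the genes differently from the 0h and 4h arrays, with the meiosis and mating lists near the median gene and a highest rho of 0.402 between an early and a late array, where a rescaling would keep the order. Genomic DNA labelled evenly would put the repeated 18S genes above the median gene, but the highest late array had them at -2.51 log2 units. Their median signal on the late arrays, 2.79 (8h A) to 12.5 (30h C), was below the 95th percentile of S. pombe signals of each array. The 18S probe sets were thus not above background there, and -2.51 is not an exact level. Unspecific binding would lift the S. pombe probe sets as well, but the meiosis list lay at least 0.582 log2 units above their 99th percentile on the late arrays; since 4h arrays also had it 0.326 to 0.776 above, this bears on the late arrays only weakly. Labelled yeast nucleic acid that holds silent genes about as much as active ones remains a possible explanation, with the lower of the lists at -0.443 log2 units from the median gene on its lowest late array. A biological change between 4h and 8h stays open as untested, because time and array appearance changed together.

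Ribosome biogenesis factors were lower and glycolysis genes higher at 4h than at 0h. The 3′ bias of 0h A as the whole cause is argued against by the medians without that array, -2.10 and 1.48, although 0h A lay apart: the 4h mean minus 0h A, B and C was -0.885, -2.16 and -2.13 for biogenesis and 2.13, 1.48 and 1.47 for glycolysis. A fit with high 18S signal as a term, for a share of rRNA in the labelled sample, gave -1.98 and 1.64. It called 52 of 64 and 13 of 17 members. At 0h only 0h B, which had the low 3′ ratio of 1.87, had high 18S signal. The term thus mixes rRNA with 3′ bias there and cannot isolate a share of rRNA. A response of the yeast to the new wort is a hypothesis that no test here addressed, and the 3′ ratio of 6.53 on 0h C leaves a wider effect of RNA quality at 0h open.

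Cytosolic ribosomal proteins were lower at 30h than at 8h. Genes at the same 8h level did not share the fall: 10000 random lists matched on that level had a lowest median of -0.16 against -1.30. Quantile normalisation had already removed a change common to genes of the same level, so this cannot weigh such a change in the deposited signals. Silent genes lay near the median gene on the late arrays, so the match does not pair active genes with active ones. A larger share at 30h of nucleic acid that holds silent genes was not tested and stays open. The dim 8h C array alone is argued against by the median without it, -1.44, with 75 of 128 members lower. A change in growth between 8h and 30h may account for it, as a hypothesis found on these same data, and differences between the 2 samplings that the labels do not record stay open.

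For each comparison of 3 with 3 arrays, 1 of 10 splits, the real one, called as many genes, too few splits for a share under 0.05. The real counts were 1295 at 4h against 0h, 3441 at 8h against 0h, 3545 at 30h against 0h, 3555 at 8h against 4h and 200 at 30h against 8h. The highest of the other splits called 0, 0, 0, 0 and 2 genes by limma, with 424, 826, 726, 31 and 586 at an unadjusted p under 0.05. For the test over 4 times, 1 of 100 drawn splits, the real one, called 4317 genes and the highest other called 3053. The real grouping never mixes early and late arrays, as drawn splits can. That share therefore cannot separate time from the difference between the arrays, and no conclusion on chance is drawn from it.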

How the results depend on the processing

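The deposited scale as an alternative, both kinds of array weights, and the fits of early or late arrays alone were chosen after the results were seen; the deposited scale had been the intended setting before the data were examined. On that scale the counts of higher and lower genes were 45 and 2609 at 4h against 0h, 221 and 4303 at 8h against 0h, 354 and 3635 at 30h against 0h, 603 and 2842 at 8h against 4h, and 3 and 2 at 30h against 8h, beside median shifts of all genes of -1.17, -2.48, -1.86, -1.28 and 0.58. The percent of calls that were higher was 1.70, 4.89, 8.87, 17.5 and 60, against 50, 47.3, 48.4, 47.6 and 25 after quantile normalisation. Median centring gave 1025 higher at 4h against 0h, and 6 higher and 43 lower at 30h against 8h. Gene-by-gene array weights gave 1769 and 1523 at 4h against 0h, and REML weights, which did not converge, 1465 and 1254 there and 109 higher at 30h against 8h. A pseudocount of 100 gave 106 higher at 30h against 8h. The cause was not tested for any of these except the deposited scale, whose shifts follow from its construction. Of 77 list calls, 2 held with an estimated correlation, and fry, which asks a different question, called 116 of 180. HSP12 at 30h against 0h reversed with median centring, to -0.485.

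Leaving out 1 array gave 320 (without 4h B) to 783 (without 0h A) higher and 353 (without 4h B) to 767 (without 0h A) lower at 4h against 0h, and 25 (without 4h B) to 255 (without 0h A) higher and 99 (without 8h A) to 313 (without 0h A) lower at 30h against 8h. Lower counts can follow from fewer arrays. The rise without 0h A was not traced further, but at 30h against 8h that array enters only through the spread and the normalisation shared by all arrays. The other counts stayed within 1.5 times, at 1494 to 1774 and 1605 to 1944 for 8h against 0h, 1563 to 1859 and 1654 to 2003 for 30h against 0h, 1500 to 1883 and 1621 to 2082 for 8h against 4h, 3955 to 4668 for the test over 4 times and 73 to 78 lists. Calls ended in at least 1 of these fits for 18 named genes at 4h against 0h (ATF1, ATG2, CIT1, CLB2, CLN2, DAL4, ERG3, GRE3, HSP12, OLE1, POT1, PRB1, PUT2, RPL3, SDH2, SOD2, SPL2 and YPK2). At 30h against 8h they ended for 9 (ATP15, CYC1, HHT1, HHT2, MSC1, PCK1, UGP1, YER187W and YMR175W-A). They also ended for RPL3 at 8h against 0h and SOD2 at 8h against 4h, and for none at 30h against 0h. No named gene called with all arrays reversed in these fits. The number of members called, counted per fit after the results were seen, moved over 1.5 times in at least 1 of these fits for 12 of 18 called lists at 4h against 0h, 6 of 9 at 30h against 8h, 1 of 17 at 8h against 4h, and 0 of 17 and 0 of 16 at 8h and 30h against 0h. Of 246 named values, 223 kept their side of the threshold, and their direction where called, with median centring. With pseudocounts of 100 and 16, 234 and 239 did, and 238 with the replicate letter as a block. The direction of values that were not called was not counted. The letters showed no pairing across all times: 2 of 18 same-letter pairs had a residual correlation over 0.1 and 4 of 12 arrays were closest to their own letter. Those 2 pairs were 8h A with 30h A (0.188) and 8h C with 30h C (0.237), while 8h B with 30h B was at -0.00695. A pairing of some samples between 8h and 30h is therefore not excluded. The early arrays alone gave 731 and 657 at 4h against 0h, and the late arrays alone 44 and 124 at 30h against 8h. Signal over background limits the genes that were dim on every array of a time, 126 at 8h and 47 at 30h.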

Other observations

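The lists and their tests below were fixed before the data were examined, but the quantile normalisation of the values they use and the counting of list members with 1 array left out were chosen after the results were seen. From 0h to 4h, 5 of 26 DNA replication genes fell and 0 rose, or 4 fell when adjusted over the list alone, and without 0h A 8 fell. The list's median was -0.48 (camera adjusted p = 0.00334, and adjusted p = 0.108 with an estimated correlation). POL30, for the sliding clamp PCNA, fell by 1.42 ± 0.25, RFC4 fell by 1.24 ± 0.23, and POL12 and POL1 of DNA polymerase alpha fell by 1.19 ± 0.24 and 1.17 ± 0.25. Of 13 phosphate response genes 4 fell and 0 rose, or 5 when adjusted over the list alone (median -0.53, camera adjusted p = 0.0128, and adjusted p = 0.161 with an estimated correlation). Without 4h A 2 fell, and without 0h A the median was -0.34. The phosphate transporter genes PHO84 and PHO89 fell by 1.95 ± 0.34 and 1.49 ± 0.36 and SPL2 fell by 1.12 ± 0.33, a call that ended without 0h A, 4h A or 4h B (highest adjusted p = 0.111). PHM8 was at -1.26 ± 0.44 (adjusted p = 0.0519, limma), called with median centring, pseudocounts of 16 and 100 and the replicate block (adjusted p of 0.0134, 0.0363, 0.0321 and 0.0386).

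Over the same interval, 8 of 20 nitrogen catabolite repressed genes rose and 0 fell, or 9 when adjusted over the list alone (median 0.67, camera adjusted p = 0.00995, and adjusted p = 0.135 with an estimated correlation), and without 4h B 3 rose. UGA1, of GABA use, rose by 1.46 ± 0.23, the proline permease gene PUT4 by 1.34 ± 0.29, DAL4 by 1.08 ± 0.27 and PUT2 by 1.07 ± 0.36. The call of DAL4 ended without 4h B (adjusted p = 0.0528), and that of PUT2 with the replicate block (adjusted p = 0.0516) and in 7 of the 12 fits without 1 array (highest adjusted p = 0.116). Of 38 autophagy and vacuolar protease genes 12 rose and 0 fell, or 16 and 1 when adjusted over the list alone (median 0.65, camera adjusted p = 0.000141, and adjusted p = 0.141 with an estimated correlation). With 1 array left out, 6 (without 4h A) to 19 (without 0h A) rose. ATG15, ATG2, LAP3 and PRB1 rose by 1.73 ± 0.30, 1.63 ± 0.41, 1.51 ± 0.33 and 1.51 ± 0.40, with PRB1 at 0.97 without 0h A. The calls of PRB1 and ATG2 ended without 4h A or 4h B, and that of PRB1 also without 4h C (highest adjusted p = 0.055 and 0.0574). Of 26 oxidative stress genes 7 rose and 1 fell, also when adjusted over the list alone (median 0.47, camera adjusted p = 0.0184, and adjusted p = 0.306 with an estimated correlation), with the catalase gene CTT1 rising by 2.56 ± 0.31, TSA2 by 2.45 ± 0.55 (1.5 without 0h A), and GPX2, which fell by 1.54 ± 0.32. That list's call ended without 0h A (adjusted p = 0.0515), and without 4h A 4 rose. Aroma formation and zinc homeostasis lists were not called at 4h against 0h (camera adjusted p = 0.0739 and 0.727).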
